A study of Mus musculus with 2 samples.

How the data were processed

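RNA was sequenced from the facial prominence of mouse embryos of strain B6NCrl at embryonic day 12.5, the stage at which the frontonasal, maxillary and mandibular swellings form the face. Per the labels, each library came from a pool of embryos of both sexes, with 120 embryos pooled for replicate 1 and 88 for replicate 2. RNA was extracted with a mirVana kit, molecules above a size limit were kept, and 10 ng went into each library. The linked protocols include a manual for a SMARTer Ultra Low RNA kit. Synthetic ERCC spike-in RNAs were added. The labels call the assay total RNA-seq. Whether ribosomal RNA was depleted could not be worked out from them. They do not say whether the libraries kept strand, so a gene and an overlapping antisense gene cannot be told apart here.

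Per its title, another series has replaced this one, so the tables used here are an older deposit. The deposited tables hold 1 row per gene or per transcript for each library. Reads were aligned to mm10 with the GENCODE M4 annotation, per the deposited notes that accompany the tables. The aligner and the quantification tool are not given in the sources used here, although the column names are those that RSEM writes. The expected count, per the file headers, is an estimated number of reads per gene, in which a read that matches several genes is shared between them. The deposited TPM values divide each count by the effective length of the gene and scale the result to the same total in each library, with the spike-ins inside that total. A second deposited TPM column holds a posterior mean, and the deposited FPKM values scale counts by length and by the depth of each library. Lengths and effective lengths, in bases, were also deposited. The effective length was a median of 99 bases under the length for the ERCC spike-ins in replicate 1. For 2218 mouse genes the effective length was 0 in both libraries, so they could not receive a value. Small noncoding RNAs are under-measured for this reason and because of the size selection.

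The gene tables had 69691 rows, of which 43346 were mouse gene IDs, 26248 were tRNA entries and 96 were ERCC spike-ins. Gene names, gene types and coordinates came from GENCODE M21, which uses the same mouse build (GRCm38, mm10) as the tables. M21 held 42462 of the mouse IDs, and the other 884 were used in totals and in the agreement of the replicates but in no gene list. Coordinates are 1-based. Of the symbols written into gene lists, Hbb-b1, Hbb-b2, Ahsp and Hist2h2bb had no matching ID, and Tp63 is the human spelling of Trp63, which was measured.

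Summed expected counts were 27890681 in replicate 1 and 39969716 in replicate 2. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.172 TPM in replicate 1 and 0.121 TPM in replicate 2 for a gene with an effective length of 1000 bases. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with under 3 expected counts in both libraries is given as not detected. Values are means ± SD over the 2 libraries (n = 2) unless a library is named.

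The series holds 1 group and no contrast between conditions. Gene lists, gene pairs and alternatives were fixed before the data were examined. For each of 36 gene lists, the median over the measured members of the mean TPM was placed among the medians of 10000 random lists of the same size, drawn from protein-coding genes, or from all annotated genes for the lists of structural and long noncoding RNAs. A list at or above percentile 97.5 or at or below percentile 2.5 was taken as apart from random lists. For the difference between the libraries, the median log2 difference of TPM with a pseudocount of 1 was placed among 10000 random lists matched on mean expression in 20 bins. These percentiles describe the 2 libraries and are not p-values, and genes of a list are not independent. For 24 gene pairs, the log2 ratio of TPM was taken in each library, and a ratio was called when its mean was over 1 or under -1 with the same sign in both libraries. No p-value was computed for ratios, since 2 libraries are too few. An exact two-sided permutation test of 2 against 2 cannot go below 0.33, and values paired within 2 libraries allow nothing smaller. Protein-coding genes with a mean TPM of 10 or more were counted as different between the libraries when their log2 difference was over 1 or under -1.

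The spread between the libraries was measured with edgeR version 4.0.16 under R version 4.3.3, as the common dispersion of an intercept-only model on expected counts rounded to whole numbers, with TMM factors, filterByExpr and the spike-ins included. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. Alternatives covered the posterior mean TPM, FPKM, counts not divided by length, other pseudocounts and minimums, RLE factors, TMM-scaled counts, other backgrounds and each library alone.

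The named genes followed a rule fixed before the data were examined. Every member of a list with 8 or fewer measured members could be named, and for longer lists the 4 members with the highest and the 2 with the lowest mean TPM. The rule also took every gene of a fixed ratio, the 15 nuclear protein-coding genes with the highest mean TPM, the 10 genes with the largest differences between the libraries (5 each way), and members of lists for tissues outside the dissection at a mean TPM of 10 or more. For isoforms it took the 8 ratio genes with the highest mean TPM and 2 or more transcripts. Genes named outside the rule are said to be chosen after their values were seen.

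The statistics were tested on simulated data. For the position of gene lists among 21474 protein-coding genes, 6.5% of 200 random lists of 15 genes came out apart from random lists, and 100% of lists drawn from the most abundant genes came out above. For the agreement of the replicates, edgeR returned a biological coefficient of variation of 4.98% where 5% was simulated (17437 genes) and 19.97% where 20% was simulated (17303 genes). For the genes that differ between the libraries, 200 changed genes were simulated. Every gene here, and in the list differences below, was given the same biological coefficient of variation of 6%. The rule took 0% of the 70 genes changed 1.5-fold, 96.7% of the 60 changed 2.5-fold, 100% of the 70 changed 4-fold and 0 of 8911 unchanged genes. With so small and even a spread that 0 could hardly be otherwise. It does not cover genes with a larger spread or with shared reads. For the list differences, 4.5% of unchanged lists came out apart from random, and 100% of lists shifted by 0.2 on the log2 scale came out above.

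Explanations of unexpected patterns were tested with gene lists written after the results were seen. Crygn was taken out of the list of other lens genes after a first run, because it was among the genes that differ, and Trpm1 was left out of the pigment genes for the same reason. The deposited tRNA rows and the gene IDs outside M21 were not analysed here beyond their totals.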

Results

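The data were 2 total RNA libraries from the facial prominence of mouse embryos at embryonic day 12.5, each from its own pool of embryos, with 1 group and no comparison between conditions. Summed expected counts were 27890681 (replicate 1, 120 embryos) and 39969716 (replicate 2, 88 embryos). In both libraries 15140 genes, 13275 of them protein-coding, reached 1 TPM. The median TPM over all protein-coding genes was 5.24. The design allows levels to be described within the tissue and the pools to be compared as libraries. Of 36 gene lists, 13 had a median above random lists, 2 had a median below and 21 lay within.

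The question for the patterning genes was which parts of the face the RNA represented. Genes of cranial neural crest-derived mesenchyme were abundant. All 16 measured members reached 1 TPM in both libraries, and the median over them was 42.7 ± 1.59 TPM. The median of their mean TPM, 41.4, lay at percentile 99.8 of random lists. Msx1, a homeobox gene of facial outgrowth (chromosome 5, 37820485 to 37824583, GRCm38), stood at 331 ± 7.67 TPM, Prrx1 at 151 ± 4.26, Pdgfra at 94.9 ± 2.42 and Prrx2 at 94.2 ± 8.49. The lowest members were Foxc1 at 13.5 ± 1.02 TPM and Tfap2a at 6.06 ± 0.396. Transcription factors of the maxillary and proximal part of the arch also lay above random lists, at percentile 99. There, Barx1 had 133 ± 62.8 TPM (chromosome 13, 48662998 to 48666507), Pitx1 105 ± 33.9, Dlx1 63.0 ± 12.9, Lhx8 55.2 ± 7.35, Dlx2 21.3 ± 4.66, Lhx6 15.6 ± 4.02 and Pou3f3 9.27 ± 0.990. In scaled counts not divided by length this list lay at percentile 96.2, under the threshold.

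The frontonasal list lay within random lists at percentile 92.2, although 6 of its 7 genes had a mean of 10 TPM or more. Alx1 stood at 113 ± 29.9 TPM (chromosome 10, 102998707 to 103030215), Six2 at 29.4 ± 2.89, Pax3 at 27.2 ± 5.23, Alx4 at 21.5 ± 2.02 and Pax7 at 1.14 ± 0.0354. The mandibular list, made of distal arch genes downstream of endothelin signalling, was also within random lists at percentile 53.6. Dlx5 at 70.7 ± 19.3 TPM and Gsc at 46.3 ± 10.4 led it, followed by Dlx3 at 17.4 ± 0.926 and Dlx6 at 8.88 ± 3.22. Hand2 was at 5.27 ± 0.262 TPM, Dlx4 at 4.38 ± 0.424, Nkx2-3 at 3.12 ± 0.177 and Hand1 at 3.00 ± 2.04. Palate genes lay above random lists at percentile 98.2, or at 95.3, within random lists, when genes at 0 were left out of the background. Osr2 (77.2 ± 0.389 TPM), Osr1 (70.9 ± 0.120), Efnb1 (59.8 ± 1.69) and Mn1 (48.0 ± 0.113) were its most abundant members, and Meox2 (11.1 ± 0.354) and Tbx22 (9.57 ± 2.62) its least abundant.

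Surface epithelium lay above random lists at percentile 99.2, with all 18 members at 1 TPM or more in both libraries. The basal keratins Krt14 (95.5 ± 6.24 TPM), Krt15 (68.8 ± 11.3) and Krt5 (63.7 ± 4.06) and the adhesion gene Epcam (58.5 ± 0.212) were highest, and Grhl2 (5.89 ± 0.537) and Itgb4 (3.41 ± 0.0354) lowest. The list fell within random lists without genes at 0 in the background (96.8) and in counts not divided by length (97.1). Genes of the tooth placode and dental epithelium lay within, at percentile 34.7, and 9 of the 12 reached 1 TPM in both libraries. Lef1 (92.2 ± 0.297 TPM), Sostdc1 (51.9 ± 2.09) and Bmp4 (34.5 ± 0.0354) were among the 4 highest. Edar (1.00 ± 0.184) and Fgf20 (0.720 ± 0.0283) were lowest.

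Cartilage genes lay at percentile 99.5, with 14 of 15 at 1 TPM or more in both libraries, and at 95.5, within random lists, in counts not divided by length. Col2a1, the main fibrillar collagen of cartilage (chromosome 15, 97975602 to 98004695), stood at 337 ± 34.0 TPM. Sox9 had 118 ± 6.09 TPM, Col9a3 118 ± 20.8 and Col9a1 110 ± 1.46, while Matn3 (1.72 ± 0.0424) and Snorc (0.795 ± 0.219) were low. The osteoblast list lay within random lists at percentile 60.7. Its matrix genes Sparc (669 ± 14.4 TPM), Col1a2 (534 ± 37.1) and Col1a1 (469 ± 63.4) are also made by other mesenchymal cells, and Runx2, the regulator of bone formation, had 26.0 ± 0.240 TPM. Bglap and Bglap2, near-identical genes for osteocalcin, were not detected. Skeletal muscle lay within at percentile 95.1, with 16 of 17 members at 1 TPM or more. Actc1 stood at 198 ± 24.2 TPM, Tnnt1 at 103 ± 12.5, Tnnc1 at 65.2 ± 13.6 and Myog at 57.5 ± 7.57, and Pax7 and Myf6 (0.610 ± 0.0849) were lowest.

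Endothelial genes lay within random lists at percentile 95.7, led by Egfl7 (82.0 ± 2.21 TPM), Plvap (51.7 ± 1.45), Sox18 (34.0 ± 3.17) and Esam (29.9 ± 2.57), with Sox17 (9.83 ± 3.07) and Tek (8.53 ± 0.580) lowest. Erythroid genes lay above random lists at percentile 100. The embryonic globin Hbb-y had 7393 ± 477 TPM, the highest mean of any nuclear protein-coding gene, and Hba-a2 had 5961 ± 383, Hba-a1 2699 ± 133 and Hba-x 1416 ± 125. Gata1 (1.70 ± 0.346) was the lowest erythroid gene. Macrophage genes lay within at percentile 60.2, with C1qb (24.0 ± 0.806 TPM), Fcer1g (19.4 ± 0.247), C1qc (14.8 ± 1.57) and Tyrobp (14.6 ± 1.19) highest and Ptprc (1.36 ± 0.325) and Fcgr1 (0.665 ± 0.0919) lowest.

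Neuronal genes lay within at percentile 86.6. Tubb3 (144 ± 31.9 TPM), Nefl (106 ± 20.2), Nefm (95.4 ± 18.4) and Stmn2 (79.4 ± 14.8) were highest, and Neurog2 (3.74 ± 0.771) was among the 2 lowest. Peripheral glia lay within at percentile 59.9, led by Fabp7 (143 ± 26.4 TPM), which radial glia also express, Erbb3 (17.3 ± 0.0849) and Sox10 (17.0 ± 0.905). Cdh19 (1.63 ± 0.0849) and S100b (1.19 ± 0.219) were lowest. Olfactory epithelium lay within at percentile 60.5, with Gap43 (105 ± 9.45 TPM), Ebf2 (25.1 ± 1.63) and Eya2 (19.1 ± 0.764) among the 4 highest. Omp, the marker of mature olfactory neurons, had 0.370 ± 0.0141 TPM.

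Hox genes, which are silent in the neural crest of the face, lay below random lists at percentile 0.015. Of 39 Hox genes, 5 reached 1 TPM in both libraries and 16 were not detected. Hoxa2 had 14.2 ± 1.82 TPM (chromosome 6, 52162417 to 52164831), Hoxd1 9.81 ± 0.0495, Hoxb2 4.30 ± 1.51 and Hoxd8 1.72 ± 0.608. Hoxc6 and Hoxc9 had 0 counts. Gut and lung endoderm genes lay below random lists at percentile 0.635, and 0 of 12 reached 1 TPM in both libraries. Vil1 (0.195 ± 0.00707 TPM), Gata4 (0.145 ± 0.0212), and Foxa3 (0.135 ± 0.0354) were the highest that were detected, Tff3 was not detected, and Cdx1 and Cldn18 had 0 counts.

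Markers of tissues outside the dissection varied. Hepatocyte genes lay within random lists at percentile 4.58. Trf, which is not specific to liver, had 16.9 ± 0.382 TPM, and Ttr had 5.46 ± 0.290, Apoa2 2.98 ± 0.163 and Afp 2.58 ± 0.0566, while Ahsg and Hnf4a were not detected. Forebrain genes lay within at percentile 14.7. Emx2 had 18.4 ± 1.82 TPM, and Nkx2-1 (2.5 ± 1.64), Fezf2 (2.15 ± 0.0919), Olig2 (1.96 ± 0.757), Sox1 (0.415 ± 0.00707) and Eomes (0.300 ± 0.325) were lower. With genes at 0 left out of the background, the hepatocyte list (0.07) and the forebrain list (1.68) fell below random lists. Cardiomyocyte genes lay within at percentile 21.9, with no mean reaching 10 TPM. Nppa had 4.64 ± 5.81 TPM, Myh7 4.28 ± 0.693, Tnni3 3.81 ± 0.212, Smpx 3.00 ± 0.0919 and Ryr2 0.325 ± 0.0354, and Nppb was not detected. The eye and pigment list lay within at percentile 55.3, and 6 of its 15 genes had a mean of 10 TPM or more. The lens crystallins Cryaa (145 ± 87.6 TPM), Cryba1 (93.2 ± 53.3), Crybb1 (58.5 ± 28.6) and Crybb3 (48.9 ± 29.2) and the pigment gene Pmel (21.8 and 39.2 TPM in the libraries) were 5 of these 6, and Rax (9.42 and 10.9 TPM) was the sixth. Crygs (0.795 ± 0.191) was low, and Crx had 3 counts in replicate 1 and 0 in replicate 2.

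Signalling genes were described as pathways. The endothelin and retinoic acid list lay above random lists at percentile 98.9, or at 95.7, within random lists, without genes at 0 in the background. Its binding proteins Crabp1 (476 ± 37.7 TPM) and Crabp2 (392 ± 7.18) led, with the receptor Rarg (101 ± 1.58) and the synthetic enzyme Aldh1a2 (79.5 ± 4.40), and Cyp26c1 (0.865 ± 0.0495) and Edn2 (0.515 ± 0.106) were lowest. The hedgehog list lay within at percentile 78.4. The co-receptor Gas1 had 235 ± 26.0 TPM, Smo 53.2 ± 1.03, Boc 30.9 ± 0.205 and Gli3 29.5 ± 0.0636, and the ligands Dhh (1.14 ± 0.325) and Ihh (0.315 ± 0.247) were lowest. The BMP and TGF-beta list lay within at percentile 89.9, and all 24 members reached 1 TPM. The target genes Id3 (511 ± 5.30 TPM), Id2 (361 ± 3.88) and Id1 (140 ± 1.18) and the receptor Tgfbr1 (67.2 ± 3.05) were highest, and Gdf6 (2.44 ± 0.318) and Tgfb1 (2.25 ± 0.629) lowest. The FGF list lay within at percentile 79.1, with Fgfr1 (131 ± 0.127 TPM), Fgfr2 (104 ± 0.106), Dusp6 (72.7 ± 0.672) and Spry2 (43.1 ± 1.45) highest and Fgf3 (0.685 ± 0.318) and Fgf4 (0.0900 ± 0.0424) lowest. The WNT list lay within at percentile 68.3. Sfrp2, a secreted WNT antagonist, had 434 ± 0.537 TPM, Lef1 92.2 ± 0.297, Wnt5a 86.4 ± 14.8 and Sfrp1 56.0 ± 1.59, and Rspo4 (0.295 ± 0.134) and Wnt1 (0.210 ± 0.156) were lowest.

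Orofacial cleft genes, the mouse orthologs of genes with variants in human cleft lip or palate, lay above random lists at percentile 99.8. Of 42, 41 reached 1 TPM in both libraries, and 24 of the 42 also belong to another list. Col2a1, Msx1 and Flna (297 ± 0.297 TPM) were among the 4 highest, and Pax7 and Vax1 (0.925 ± 0.0212) lowest. Proliferation genes lay at percentile 100, and all 19 had a mean of 10 TPM or more. Cdk1 had 311 ± 7.92 TPM, Birc5 260 ± 4.54, Rrm2 246 ± 10.2, Top2a 238 ± 1.37, Bub1 58.3 ± 1.19 and Mki67 39.2 ± 1.06. Imprinted genes also lay at percentile 100, with Nnat (1801 ± 319 TPM), Cdkn1c (1059 ± 6.80), Mest (1023 ± 11.5) and Meg3 (618 ± 86.6) highest and Zim1 (2.88 ± 0.148) and Rtl1 (2.10 ± 0.368) lowest. Immediate early and stress genes lay within at percentile 55.5. Hspa8 (2117 ± 35.4 TPM), which is made constitutively, Jun (95.0 ± 3.08), Ier2 (79.1 ± 1.19) and Jund (57.5 ± 2.38) were highest, and Hspa1b (0.290 ± 0.0141) and Fosb (0.0300 ± 0.0141) lowest. The sex-linked list lay within at percentile 85.0, and its 5 genes were present in both mixed-sex pools. Eif2s3y had 37.2 ± 2.24 TPM, Xist 24.4 ± 4.07, Ddx3y 23.2 ± 5.26, Uty 16.0 ± 1.81 and Kdm5d 12.0 ± 3.30.

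**Figure D1:**
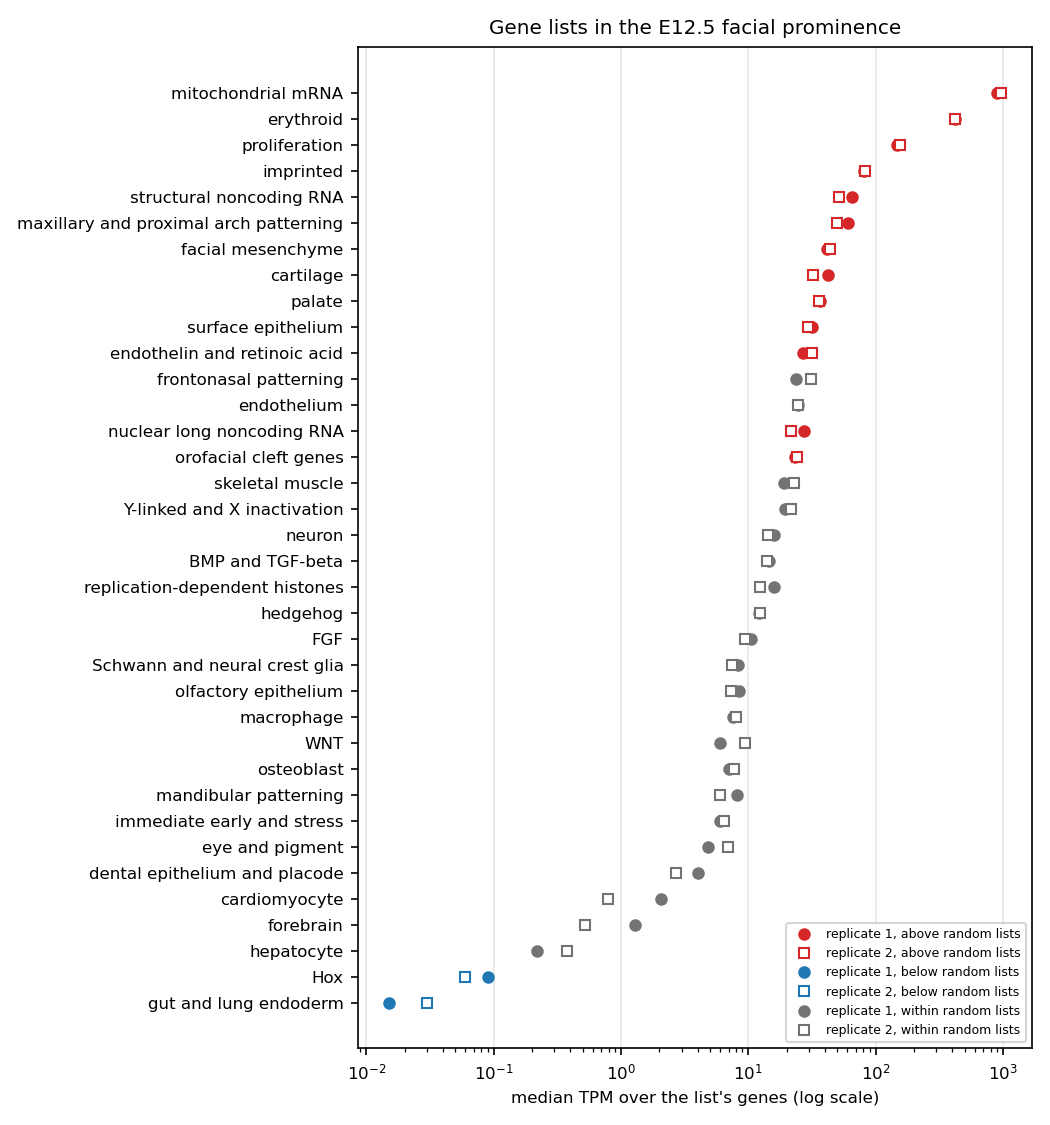
Median TPM over the genes of each of the 36 lists (x axis, log scale) in replicate 1 (filled circles) and replicate 2 (open squares), with red for lists above random lists, blue for lists below and grey for lists within. The mitochondrial mRNA list has the highest median (895 and 974 TPM), and the gut and lung endoderm list the lowest (0.0150 and 0.0300 TPM).

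Fixed pairs of genes were compared within each library, and 14 of 24 ratios were called. Red blood cell genes had the embryonic profile at the beta locus, where Hbb-y and Hbb-bh1 together were 5.94-fold above the adult genes Hbb-bs and Hbb-bt (log2 ratio 2.57 ± 0.05). At the alpha locus the embryonic Hba-x was 6.12-fold below the adult Hba-a1 and Hba-a2 (-2.61 ± 0.04, or -2.09 in counts not divided by length). The adult alpha genes are near-identical, so only their sum is certain. Hand2, a gene of the distal mandible, was 23.8-fold below Barx1 (-4.57 ± 0.78; -5.13 without replicate 2, -4.02 without replicate 1 and -3.86 in counts not divided by length). Msx1 was 12.3-fold above Msx2 (3.62 ± 0.13). The mesenchymal pair Prrx1 and Pdgfra was 3.06-fold above the epithelial pair Epcam and Cdh1 (-1.61 ± 0.04 for epithelium over mesenchyme, or -2.63 in counts not divided by length). Sox9 was 4.55-fold above Runx2 (2.19 ± 0.06), and Myog was 2.47-fold above Myod1 (1.30 ± 0.14), or 0.97 on the log2 scale in counts not divided by length, which is under the threshold.

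Receptors stood above their ligands in both such pairs. Ptch1 was 12.7-fold above Shh (3.67 ± 0.06, or 4.99 in counts not divided by length and 2.95 with a pseudocount of 1 TPM), and Ednra was 28.5-fold above Edn1 (4.84 ± 0.42, or 5.47 in such counts and 4.11 with a pseudocount of 1 TPM), whose own level was 1.47 ± 0.346 TPM. Wnt5a was 5.47-fold above Wnt5b (2.45 ± 0.13, or 3.43 in such counts). Bmp4 was 2.12-fold above Bmp2 (1.09 ± 0.09), but the log2 ratio was 0.11 in counts not divided by length. For Fgf8 and Aldh1a2 a single library decided the call. Fgf8 was 2.09-fold below Fgf10 (-1.07 ± 0.62), with -0.63 without replicate 2 and -3.29 in counts not divided by length. Aldh1a2 was 2.03-fold above Aldh1a3 (1.02 ± 0.45), with 0.71 without replicate 1.

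The other 10 ratios were not called. Dlx5 and Dlx6 stood at -0.10 ± 0.11 (-0.74 in counts not divided by length) against Dlx1 and Dlx2, Col2a1 at -0.47 ± 0.34 against Col1a1, Pdgfra at 0.82 ± 0.07 against Pdgfrb and Fgfr1 at 0.34 ± 0.0029 against Fgfr2. Bmp4 stood at 0.52 ± 0.06 against Bmp7, Tgfb2 at 0.80 ± 0.09 against Tgfb3, Igf2 at 0.58 ± 0.04 against H19, Prrx1 at 0.68 ± 0.17 against Prrx2 and Twist1 at 0.35 ± 0.07 against Twist2. Xist against Ddx3y had 0.49 in replicate 1 and -0.32 in replicate 2. In counts not divided by length, Pdgfra over Pdgfrb (1.11), Prrx1 over Prrx2 (2.85) and Xist over Ddx3y (2.28) passed the threshold, and Bmp4 over Bmp7 changed sign (-0.15).

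**Figure D2:**
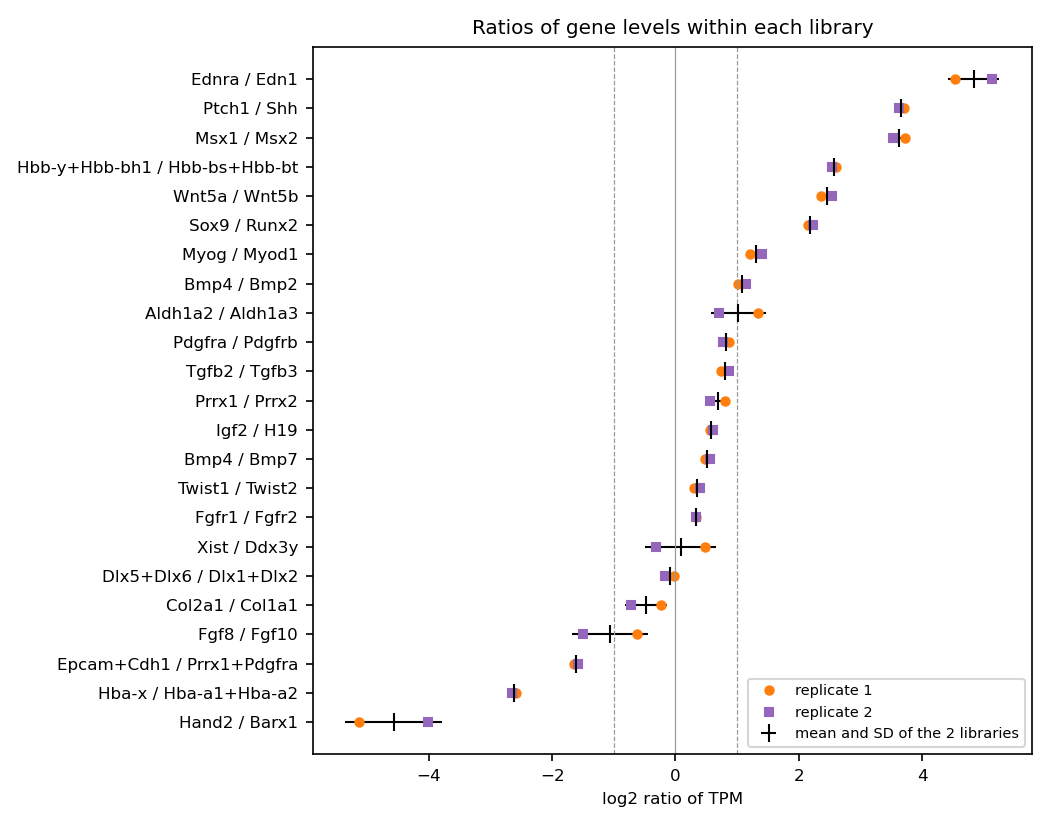
Log2 ratio of TPM (x axis) for fixed pairs in replicate 1 (circles) and replicate 2 (squares), with the mean and SD of both as a black mark and line and dashed lines at -1 and 1. Ednra over Edn1 lies highest, at 4.84, and Hand2 over Barx1 lowest, at -4.57.

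The question for RNA classes was what a total RNA library held besides messenger RNA. The labels leave open whether ribosomal RNA was depleted, so the shares describe the deposited tables and not the RNA of the tissue. Nuclear protein-coding genes took 80.2 ± 0.267% of TPM, long noncoding genes 2.46 ± 0.06%, mitochondrial genes 2.35 ± 0.0860%, pseudogenes 4.48 ± 0.0189% and miscellaneous RNAs 2.11 ± 0.159%. Malat1 (5752 ± 301 TPM), Gm42418 (4541 ± 84.0) and Gm26917 (4364.5 ± 166), the Gm genes chosen after their values were seen, led the long noncoding genes. That share therefore rests largely on few genes. Whether Gm42418 and Gm26917 hold reads of ribosomal RNA was not tested. In expected counts, pseudogenes held 1.29% and miscellaneous RNAs 0.262%, because TPM gives short genes more weight. Spike-ins took 6.88% of TPM in replicate 1 and 7.57% in replicate 2. The 10 most abundant genes of each library held 6.99 ± 0.226% of the TPM outside spike-ins. Actb (5631 ± 79.1 TPM), Ftl1 (4396 ± 120), Ppia (4228 ± 18.7), Hist1h2ap (4103 ± 68.2), Eef1a1 (3451 ± 111), Tmsb10 (3331 ± 35.3), Ubb (2832 ± 28.4), Rpl41 (2766 ± 91.3), Ptma (2626 ± 93.7), Actg1 (2622 ± 28.3), H3f3a (2604 ± 2.40) and Tmsb4x (2578 ± 99) were the 12 nuclear protein-coding genes other than globins among the 15 highest. Several of them have many processed pseudogenes, so their share of reads is uncertain.

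Among RNAs without a poly(A) tail, the 67 replication-dependent histone genes took 0.582 ± 0.0166% of TPM. Hist1h2ap (4103 ± 68.2 TPM), which is outside the fixed list, was by far the highest of them. The fixed histone list lay within random lists at percentile 91.6, or 31.6 in counts not divided by length, with Hist1h4d (362 ± 6.90 TPM), H2afx (338 ± 10.1), Hist1h2ae (259 ± 21) and Hist1h2bc (62.6 ± 1.36) highest and Hist1h2be (3.25 ± 0.0707) and Hist1h4a (0.865 ± 0.0919) lowest. H2afx is in the fixed list but not among the 67 genes above, so its level is not taken as that of an RNA without a poly(A) tail. Histone genes are near-identical copies, so single values are uncertain. Structural noncoding RNAs lay above random lists at percentile 99.9, but at 90.7 in counts not divided by length. Rn7s1 and Rn7s2, identical copies of the signal recognition particle RNA, had 10188 ± 738 TPM each, the same value because reads were shared out. Rn7sk had 371 ± 61.7 TPM, Rpph1 111 ± 18.7, Rmrp 5.14 ± 1.03 and Terc 0.250 ± 0.354. Rny1 and Rny3 had 0 counts and are shorter than the size limit of the libraries. The list named nuclear long noncoding RNA lay at percentile 99.7, or at 96.4, within random lists, without genes at 0 in the background. Its members are long noncoding RNAs, and their place in the cell was not measured. Malat1 (5752 ± 301 TPM), Meg3, Gas5 (534 ± 20.8) and H19 (388 ± 20.1) were highest, and Kcnq1ot1 (5.14 ± 0.290) and Neat1 (4.80 ± 0.417) lowest. Mitochondrial messenger RNAs lay at percentile 100. mt-Atp6 had 5067 ± 194 TPM, mt-Atp8 4495 ± 477, mt-Nd1 1820 ± 83.9, mt-Cytb 1809 ± 132, mt-Nd3 256 ± 62.8 and mt-Nd4l 78.4 ± 33.9. Nuclear pseudogenes of the mitochondrial genome share reads with them.

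Transcript tables were compared for isoforms. Of 6880 protein-coding genes with a mean TPM of 10 or more and at least 2 transcripts, 6441 (93.6%) had the same most abundant transcript in both libraries, and it held a median of 67.7% of the gene's TPM. Col1a1 was almost all its full-length transcript Col1a1-201 (99.5 ± 0.140%). Col2a1 was split between the protein-coding Col2a1-201 (64.9 ± 0.587%) and Col2a1-202 (27.7 ± 1.16%). Igf2 was split between Igf2-208 (35.1 ± 0.386%), annotated as a processed transcript, and the protein-coding Igf2-203 (35.1 ± 0.973%). The higher of these changed from Igf2-208 in replicate 1 (35.4% against 34.4%) to Igf2-203 in replicate 2 (35.8% against 34.9%). H19 was split between H19-202 (44.3 ± 4.52%) and H19-205 (31.4 ± 4.44%). Hba-x-201 held 75.8 ± 0.353% of Hba-x, and Hba-a2-201 held 100% of Hba-a2. For Hba-a1 and Hbb-bs the most abundant transcript was annotated as a retained intron, Hba-a1-202 (78.0 ± 0.778%) and Hbb-bs-202 (69.2 ± 0.533%). The adult globin genes share reads with near-identical copies, so these shares are uncertain, and the files give no error for the split within a library.

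The libraries were then compared with each other. Across 43346 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.995 and Spearman's rho 0.953. The biological coefficient of variation from edgeR was 6.27% over 17332 genes. Over 17257 genes with 10 or more counts in both, the chi-square of the counts was 5.78 times its degrees of freedom, so the libraries differed by more than counting noise, which separately amplified libraries of the same RNA could also do. The median log2 difference of 61 spike-ins, replicate 1 minus replicate 2, was -0.13 with an SD of 0.24.

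Among 9111 protein-coding genes with a mean TPM of 10 or more, 11 differed by over 1 on the log2 scale, 9 of them higher in replicate 2. Crystallin genes, most of them of the lens, made up 5 of the 9. Cryaa had 82.9 TPM in replicate 1 and 207 in replicate 2 (log2 difference -1.31; chromosome 17, 31677807 to 31681733), Crybb3 28.2 and 69.5 (-1.27), Crygn 5.45 and 15.2 (-1.33), and the list members Cryba1 55.5 and 131 (-1.22) and Crybb1 38.3 and 78.7 (-1.02). Aldh1a1, an enzyme of retinoic acid synthesis, had 8.03 and 25.2 TPM (-1.53). Gm13304 had 0 and 411 counts (-4.55); it belongs to a cluster of near-identical chemokine genes, so its value is uncertain. Trpm1 and Hist1h3h, named after their values were seen, completed the 9. Oc90 (43.4 and 18.9 TPM, 1.16) and Mamdc4 (13.9 and 6.32 TPM, 1.03) were higher in replicate 1, although Mamdc4 had 0.65 in TMM-scaled counts, under the threshold. Barx1 (177 and 88.6 TPM, 0.99), Dvl1 (13.9 and 6.83 TPM, 0.93) and B230307C23Rik (26.8 and 13.7 TPM, 0.92, or 0.51 in TMM-scaled counts) came next. With 1 library per pool these differences have no replicate check, and the count was 34 at a minimum mean of 1 TPM and 3 at a minimum of 50 TPM.

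Gene lists moved in both directions. Against lists matched on expression, 11 of 36 lists were higher in replicate 1 and 7 in replicate 2, where 1.8 would be apart by chance if genes varied independently. Maxillary and proximal arch genes were higher in replicate 1 in 6 of 7 members (median log2 difference 0.43, percentile 100), with Pitx1 at 129 and 81.4 TPM and Dlx1 at 72.1 and 53.9. The mandibular list was higher in replicate 1 (0.12, 97.8, or 95.9 with the posterior mean TPM), with Dlx5 at 84.4 and 57.1 TPM and Gsc at 53.7 and 38.9, while Hand1 was at 1.56 and 4.44. The neuron list was higher in 15 of 16 members (0.30, percentile 100), with Tubb3 at 167 and 121 TPM. Cartilage was higher in 14 of 15 members (0.21, percentile 100, or 0.12 in TMM-scaled counts), with Col9a3 at 133 and 104 TPM. Forebrain genes were higher in 8 of 12 members (0.25, percentile 99.9, or 0.55 with a pseudocount of 0.1 and 0.19, at percentile 96.9, for members at 1 TPM or more), with Nkx2-1 at 3.66 and 1.34 TPM. Other lists higher in replicate 1 were structural noncoding RNA (0.15, percentile 100, or 0.33 with the posterior mean TPM and 0.34 for members at 1 TPM or more), erythroid (0.13, 100), nuclear long noncoding RNA (0.11, 99.5), surface epithelium (0.07, 99.3), replication-dependent histones (0.07, 99.2, or 91.7 in TMM-scaled counts) and imprinted genes (0.05, 98.8).

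In replicate 2 the eye and pigment list was higher in 14 of 15 members (-0.78, percentile 0). Skeletal muscle was higher in 16 of 17 members (-0.27, percentile 0), with Tnnc1 at 55.6 TPM in replicate 1 and 74.8 in replicate 2. The frontonasal list was higher in 5 of 7 members (-0.18, 0.05), with Alx1 at 91.9 and 134 TPM and Pax3 at 23.5 and 30.9. Facial mesenchyme (-0.11, 0.04), osteoblast (-0.08, 1.72), mitochondrial mRNA (-0.11, 0.01) and the sex-linked list (-0.22, 0.06) were also higher in replicate 2. Osteoblast genes lay within random lists in TMM-scaled counts (3.87) and for members at 1 TPM or more (8.14). In the sex-linked list the Y-linked genes were all higher in replicate 2 (Ddx3y 19.5 and 26.9 TPM, Kdm5d 9.64 and 14.3), and Xist was higher in replicate 1 (27.3 and 21.5 TPM).

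The other 18 lists lay within matched random lists. Their percentiles were 62.8 for palate, 3.07 for Hox, 57.1 for dental epithelium, 95.7 for endothelium, 37.4 for macrophage, 83.3 for peripheral glia and 74.4 for olfactory epithelium. They were 29.7 for hepatocyte, 74.2 for cardiomyocyte, 51.4 for gut and lung endoderm, 4.5 for proliferation, 62.2 for hedgehog, 70.3 for BMP and TGF-beta, 73.1 for FGF, 4.11 for WNT, 25.5 for endothelin and retinoic acid, 77.4 for orofacial cleft genes and 23.9 for immediate early and stress genes. In some alternatives 2 of these lists were apart from random lists, higher in replicate 2. These were Hox over members at 1 TPM or more (-0.43, percentile 0.02) and WNT in TMM-scaled counts (1.77) and with the posterior mean TPM (0.7).

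**Figure D3:**
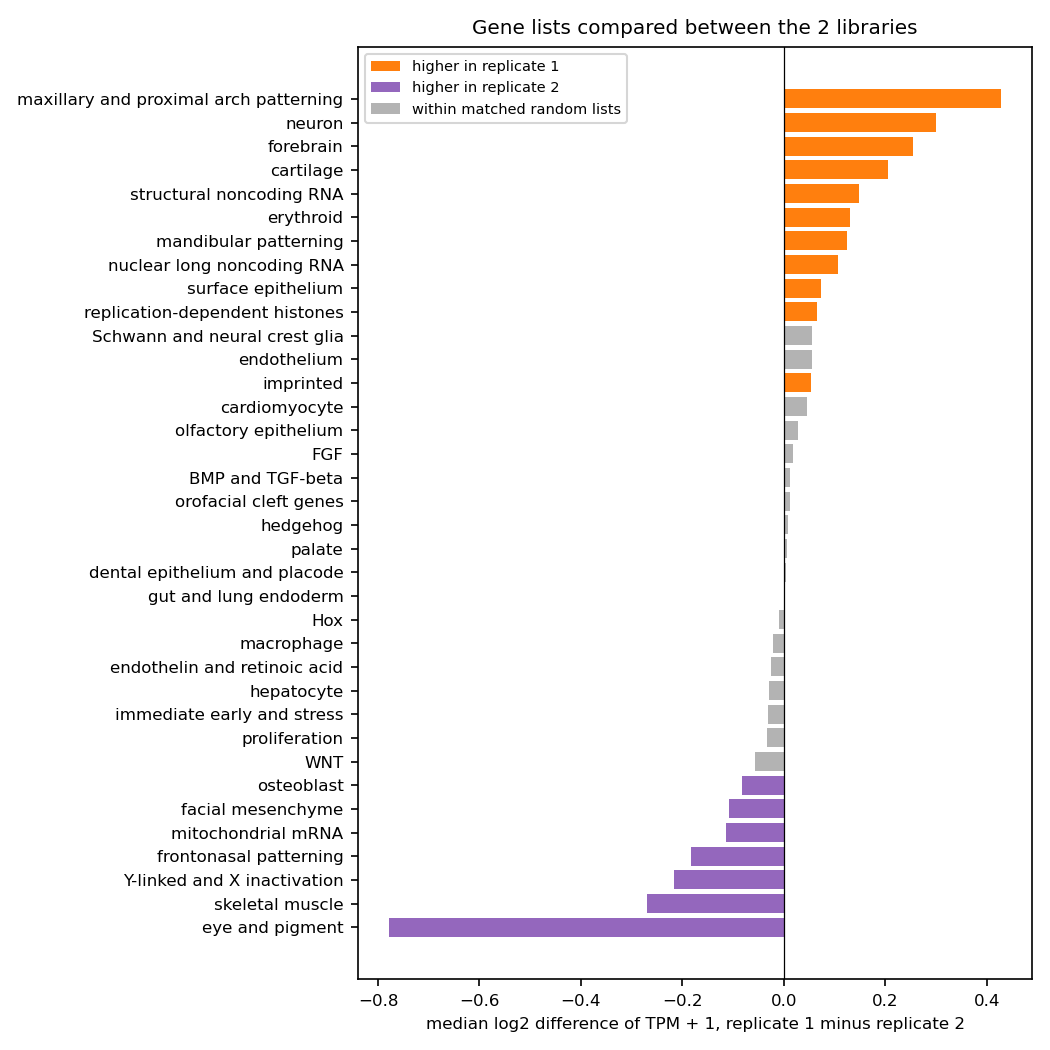
Median log2 difference of TPM + 1, replicate 1 minus replicate 2 (x axis), for each of the 36 lists, in orange for lists higher in replicate 1, purple for lists higher in replicate 2 and grey for lists within matched random lists. Maxillary and proximal arch genes lie at 0.43 and eye and pigment genes at -0.78.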

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

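All tests of explanations in this part were chosen after the results they bear on were seen. Counts were also present outside the main measurement. The tRNA rows summed to 40 expected counts in replicate 1 and 47.0 in replicate 2, over 26248 annotated tRNA entries, and the most abundant single entry had 18 and 32 counts, above the 3 that a count of 0 allows. The gene IDs outside M21 held 0.317% of the expected counts in replicate 1 and 0.300% in replicate 2.

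Lens and pigment genes were higher in replicate 2, and the labels give no group that would explain it. A depth or scaling factor per library moves every gene alike and cannot open the gap of -0.77 between the median of this list and that of all 9111 protein-coding genes at 10 TPM or more, and a GC content trend is argued against by the list's median of -0.73 with that trend removed. A candidate explanation is more lens in the pool of replicate 2, since 17 other lens genes, none in the fixed list, had a median of -0.54 (percentile 0), with 14 higher in replicate 2, Cryab (15.1 and 21.4 TPM) and Cryge (13.4 and 24.1 TPM) being the most abundant and chosen after their values were seen; genes of the gamma crystallin family share reads. More lens would not raise pigment genes, and 5 of these outside the fixed list and outside the genes that differ, all under 10 TPM, had a median of -0.28 (percentile 0.91). Whether more neural retina came with it stays open, because 12 retina genes, 4 of them in the fixed list and several also expressed in the face, went both ways with a median of -0.095, and the bound that left this open was set after its percentile of 2.37 was seen.

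Maxillary and proximal arch genes were higher in replicate 1 and frontonasal genes higher in replicate 2, which opened a gap of 0.61 between the list medians. The other arch list, mandibular, is not part of that gap. Its median was smaller, at 0.12, with 5 of 8 members higher in replicate 1. A scaling factor per library moves the maxillary and frontonasal lists alike and cannot open the gap of 0.61, and with the GC content trend removed the gap was 0.60. More ventral forebrain in the pool of replicate 1 might have raised the Dlx genes, but 6 subpallial neuron genes carried a summed excess of 0.81 TPM where Dlx1, Dlx2, Dlx5 and Dlx6 carried 56.7 TPM. The fixed forebrain list was still higher in replicate 1 in 8 of 12 members (median 0.25, percentile 99.9). The summed excess therefore bears on the Dlx genes only, and not on whether that pool held more forebrain. Unequal proportions of arch and frontonasal tissue in the pools stay open as a hypothesis, without a test.

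Outside the fixed lists, 12 genes with a mean TPM of 10 or more were over 0.8 higher on the log2 scale in replicate 1, among them Dvl1, Axin1 (23.2 and 12.7 TPM), Gna12 (47.7 and 25.1 TPM) and Selenon (40.7 and 22.5 TPM), chosen after their values were seen. Across the 9111 genes the log2 difference rose with GC content (Spearman's rho 0.27, across genes, which are not independent), but only from -0.05 in the lowest to 0.05 in the highest of 20 bins. With the GC trend removed, the median of the 12 genes was 0.88, and in counts not divided by length it was 0.86, so neither GC content nor transcript lengths assigned differently accounts for the whole difference of the set. In those counts single genes moved both ways, down for Mamdc4 (0.65), B230307C23Rik (0.51), Atoh7 (0.69) and Axin1 (0.74) and up for Gm14296 (1.39). These values carry a pseudocount of 1 on the scaled counts, which shrinks the difference of genes with few reads. Atoh7 had only 92 and 66 counts, so its drop does not bear on length. The pseudocount can also account for part of the drop of Mamdc4 (207.7 and 174.3 counts) and B230307C23Rik (116 and 104 counts). For single genes lengths stay open. No biological explanation was tested.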

How the results depend on the processing

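No alternative reversed a called direction. The alternatives were fixed before the data were examined. Of 216 list positions under alternatives, 206 kept their side of the thresholds. In scaled counts not divided by length, the percentile was 96.24 for maxillary and proximal arch genes, 97.08 for surface epithelium, 95.46 for cartilage and 90.75 for structural noncoding RNA. With genes at 0 left out of the background, it was 95.31 for palate, 96.78 for surface epithelium, 96.36 for nuclear long noncoding RNA, 95.68 for endothelin and retinoic acid, 1.68 for forebrain and 0.07 for hepatocyte. The last alternative removes unexpressed genes and so raises the bar. Of 120 ratios under alternatives, 108 kept their call. In expected counts the log2 ratio was 0.97 for Myog over Myod1, 1.11 for Pdgfra over Pdgfrb, 0.11 for Bmp4 over Bmp2, 0.63 for Aldh1a2 over Aldh1a3, 2.85 for Prrx1 over Prrx2 and 2.28 for Xist over Ddx3y, since counts weigh long transcripts more. Fgf8 over Fgf10 was -0.89 with a pseudocount of 1 TPM and -0.95 with the posterior mean TPM, and Aldh1a2 over Aldh1a3 was 1.0 with the posterior mean TPM. Leaving out each library gave 0.51 to 1.57 for a called ratio not described here, -1.50 to -0.63 for Fgf8 over Fgf10 and 0.71 to 1.34 for Aldh1a2 over Aldh1a3.

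Pearson's r was 0.9868 with a pseudocount of 0.1 and 0.9865 over genes at 1 TPM or more in either library, and the coefficient of variation was 6.75% with no filter on low counts. Of 143 list differences under alternatives, 135 kept their side. The percentile was 95.92 for the mandibular list with the posterior mean TPM, 3.87 for osteoblast, 91.67 for histones and 1.77 for WNT in TMM-scaled counts, 0.7 for WNT with the posterior mean TPM, and 0.02 for Hox, 8.14 for osteoblast and 96.9 for forebrain over members at 1 TPM or more; the cause was not tested. No scaling moved the median of all genes by over 0.1. The count of genes that differ was 34 at a minimum mean of 1 TPM and 3 at 50 TPM, by construction. Percents of expected counts were 91.36 for nuclear protein-coding, 1.13 for mitochondrial, 1.29 for pseudogene, 0.26 for miscellaneous, 3.06 for spike-in, 0.15 for histone and 0.62 for globin genes. Without mitochondrial genes and spike-ins, percents of TPM were 88.67 for protein-coding, 2.72 for long noncoding, 4.96 for pseudogene, 2.33 for miscellaneous, 0.64 for histone and 2.13 for globin genes. The dominant isoform held a median of 65.0% with the posterior mean TPM and 78.8% among protein-coding transcripts only. No paired analysis between groups was possible because the series has 1 group. The difference of the gut and lung endoderm list over members at 1 TPM or more gave no value, since no member was left. Depth limits the Hox and endoderm lists, where 16 of 39 and 8 of 12 members had under 3 counts in both libraries.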

Other observations

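Gene families outside the fixed comparisons were looked at after the data were seen, and their members were chosen after their values were seen. Among cofactors of homeobox proteins, Meis1 stood at 92.1 ± 2.37 TPM and Meis2 at 59.0 ± 0.233. Of 19 Sox genes, 15 reached 1 TPM in both libraries, and Sox11 (205 ± 3.53 TPM) and Sox4 (122 ± 6.63) stood above Sox9. Of 44 Fox genes, 27 reached 1 TPM, and Foxp1 (104 ± 11.3 TPM), Foxn3 (84.3 ± 4.86) and Foxp2 (50.7 ± 5.17) were higher than the mesenchymal Foxf1 (29.3 ± 0.629). Among 13 Tbx genes, Tbx3 led with 44.0 ± 3.05 TPM, followed by Tbx2 at 17.4 ± 0.686 and Tbx1 at 17.1 ± 1.23. Irx3 (35.3 ± 7.18 TPM) and Irx5 (25.5 ± 3.68), neighbours on chromosome 8, were the highest of 6 Irx genes.

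Of 44 collagen genes, 35 reached 1 TPM in both libraries. Col3a1 stood at 1003 ± 1.34 TPM, above Col1a2, Col1a1 and Col2a1, and Col26a1 at 198 ± 1.47. Of 53 keratin genes, 11 reached 1 TPM, the highest after Krt14, Krt15 and Krt5 being Krt8 (45.9 ± 7.18 TPM), Krt18 (41.6 ± 2.03) and Krt19 (15.7 ± 1.42). All 22 ephrin and Eph receptor genes reached 1 TPM, with Ephb4 (74.0 ± 2.26 TPM), Efna5 (64.1 ± 5.75), Ephb3 (63.9 ± 2.10) and Epha7 (62.3 ± 0.827) highest, and 18 of 20 semaphorin genes did, led by Sema3f (43.4 ± 0.481 TPM). Pax6, an eye and nasal gene, had 11.3 TPM in replicate 1 and 17.1 in replicate 2, and Pax9 had 16.5 and 13.4 TPM.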
